A study of Homo sapiens with 6 samples.

How the data were processed

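The series held 6 RNA sequencing libraries labelled as THP-1 cells treated with PMA, 3 labelled wild type and 3 labelled CST3 knockout, all with 1 batch label. Per the labels' protocols, RNA was extracted with TRIzol, mRNA was captured on oligo(dT) beads and fragmented, and libraries were made with a BGI kit. The authors deposited 1 table for the series with 18454 genes, identified by NCBI Gene number and symbol. Per the file headers it held read counts per gene, which were estimated counts, since 56.0% of values, zeros included, were exact whole numbers as printed and the rest had decimals. The authors also deposited TPM values, scaled for gene length and to the same total in each library, and FPKM values, scaled for gene length and library size, per the file headers. Coordinates follow GRCh38, and the build was GRCh38.p13 per the submitters' processing notes. The aligner, the counting program and the gene annotation were not given in the sources used here. Columns were assigned to samples by group and replicate number in their names, and 6 columns of per-sample values, which held normalized read counts, were not used. Of genes in the lists, 49 were not analysed here because they had no row, and the list of 13 mitochondrially encoded genes had 0 genes to test.

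The test, its design, the gene lists, the rule for named genes and most alternatives were fixed before the data were examined. Estimated counts were rounded to whole numbers and tested with edgeR 4.0.16 in R 4.3.3 (filterByExpr, TMM normalization, robust quasi-likelihood fit). The test was two-sided, with group as the only term and a Benjamini-Hochberg adjusted p of 0.05 over 14669 genes. A prior count of 2 entered log2 CPM values, such as those behind the trends and principal components. It did not enter the main test or its fold changes. CPM values are counts scaled to the TMM-scaled library total, with means and SDs over 3 libraries. For edgeR, the SE was derived as the absolute log2 fold change divided by the square root of the test's F statistic. Depth was similar, with 18507220 to 19097151 counts per library and 342 genes at 0 in all 6. A gene of median effective length at 10 TPM gave 304 to 374 counts. Where a group was at 0, the fold was computed against a floor of 3 counts per library, which covers counting error only. Replicates were compared by a chi-square statistic per gene of their counts. It was 3.40 to 6.15 between wild type libraries and 26.0 to 101 between knockout-labelled libraries, against 1 from sampling noise alone, so no pair was merged as 1 library deposited again. This does not show that the libraries came from separate cultures.

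Named genes were CST3, the 10 largest increases and 10 largest decreases among genes past the threshold with at least 5 CPM in the higher group, groups that did not overlap and a named symbol, up to 4 genes per list past the threshold with at least 1 CPM, all tested cathepsins and cystatins, and the highest-expressed members that did not pass. Of these, a selection was printed, and some genes are not reported here. Which marker genes to give in TPM was chosen after their values were seen. Lists with at least 5 tested genes were compared with all other genes by camera in limma 3.58.1 with a preset correlation of 0.01, adjusted over 35 lists, and CST3 was left out of every list. Counts adjusted over the list alone used the same p-values. Pan-leukocyte, embryonic kidney line, neuroblast, hepatocyte and melanocyte lists were added after the first look at the data and were used for levels only. Of the 13 embryonic kidney line genes, 8 were put on the list before their own values had been looked at.

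Transcript GC content came from GENCODE 29, to which 98.6% of genes were matched by NCBI Gene number, and effective lengths were the median over libraries of the length implied by the estimated counts and FPKM. In the correction, robust spline trends (5 degrees of freedom, MASS 7.3.60.0.1) of each library on GC content and log effective length entered the edgeR fit as offsets. Counts of overlapping or near-identical genes were summed before another fit. Alternatives were DESeq2 1.42.0, limma-voom, DESeq2 size factors or library totals in place of TMM, no filter or at least 5 CPM in 3 libraries, the replicate number as a block, thinning to the smallest library, each library left out, limma on log2(TPM + 1) and log2(TPM + 0.1), edgeR tests against 1.5-fold and 2-fold changes, and camera with estimated correlation and fry for lists.

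The code was tested on simulated counts for the 14669 genes with this design. Of 100 genes changed 2-fold, edgeR recovered 100.0% and called 11 unchanged genes, DESeq2 called 6 and limma-voom 10. With a GC and length trend added to 1 group, edgeR called 9578 unchanged genes without correction and 13 with it. Camera called 2 of 200 random lists and the shifted list. Dispersions came from the wild type libraries alone, which varied less than the knockout-labelled libraries, and genes were drawn independently. Changed genes had at least 5 CPM in wild type, and the added trend had the form that the correction fits. These counts therefore check the code and are not error rates for these data.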

Results

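Gene expression was measured by RNA sequencing of poly(A)-selected RNA from cells that the labels call THP-1, a human monocytic leukaemia line, treated with the phorbol ester PMA for differentiation toward macrophages. Per the labels, 3 libraries came from cells with intact CST3 (wild type) and 3 from CST3 knockout cells, and the comparison asked how loss of CST3 alters gene expression in such macrophages. CST3 encodes cystatin C, a secreted inhibitor of cysteine cathepsins. The columns deposited for the second group carried a name usual for RNA interference, so that group is called the libraries labelled CST3 knockout, or knockout-labelled. Library totals were 18507220, 18824636 and 18913977 estimated counts in wild type replicates 1, 2 and 3 and 18757612, 19097151 and 18652248 in the knockout-labelled libraries, and 16708 to 17163 genes per library had a count. The labels called the samples biological replicates without saying whether they came from separate cultures, so p-values measure the spread between these 6 libraries, which may be technical.

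CST3 RNA was lower in the knockout-labelled libraries but remained present in all 3 of them. The gene (NCBI Gene 1471) lies on the minus strand of chromosome 20, from 23626706 to 23638473 in GRCh38. It had 2695, 3065 and 2782 estimated counts in wild type replicates 1, 2 and 3, and 1209, 1771 and 1720 in knockout-labelled replicates 1, 2 and 3. The mean level was 162 ± 12.7 library-scaled counts (CPM; SD, n = 3) in wild type and 78.2 ± 16.7 CPM (SD, n = 3) in the knockout-labelled libraries. The log2 fold change was −1.05 ± 0.17 (SE), with an edgeR adjusted p of 0.00443. The table held gene totals, so reads over an edited part of the gene were not separated from the rest, and RNA of an edited allele would still be counted.

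**Figure D1:**
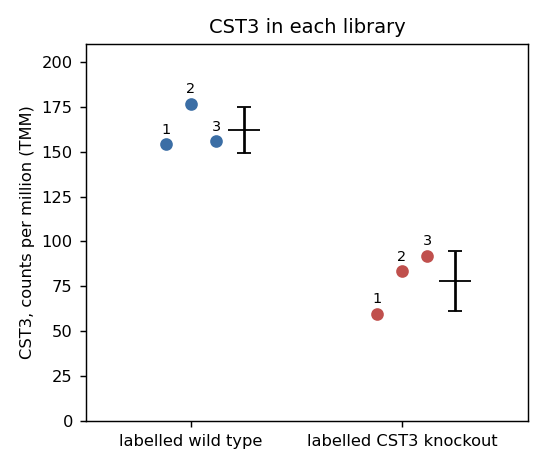
CST3 level in CPM on the vertical axis for each of the 6 libraries, as points, with group means and SDs (n = 3). All 3 wild type libraries lie above all 3 knockout-labelled libraries, with means of 162 and 78.2 CPM.

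Transcripts typical of leukocytes and macrophages were near the floor in all 6 libraries, while KRT8, KRT18, UCHL1 and CDKN2A were abundant. Of 12 epithelial markers, 2, KRT8 and KRT18, reached 10 TPM in all 6 libraries, and of 7 neuroblast genes measured 0 did. Among these 7, GATA3 and ISL1 had 15.9 ± 1.24 and 12.6 ± 2.56 TPM (SD, n = 3) in the knockout-labelled libraries. In wild type they had 7.58 ± 0.821 and 8.19 ± 0.734 TPM. PTPRC, which encodes the pan-leukocyte antigen CD45, had 0.957 ± 0.445 TPM, a level scaled for gene length and library total (SD, n = 3), in wild type and 0.980 ± 0.193 TPM in the knockout-labelled libraries. SPI1, the transcription factor PU.1 of myeloid cells, had 0.397 ± 0.101 and 0.477 ± 0.0839 TPM, and the beta-2 integrin gene ITGB2 had 0.247 ± 0.0833 and 0.230 ± 0.0866 TPM. The scavenger receptor gene CD163 had 0.00667 ± 0.0115 TPM in wild type and was at 0 in the knockout-labelled libraries. Of 42 pan-leukocyte and macrophage genes measured, 1, APOE, reached 10 TPM in all 6 libraries, and the median of their mean levels was 0.531 TPM. CORO1A had 32.8 ± 0.920 TPM in wild type and 13.8 ± 6.17 TPM in the knockout-labelled libraries. The keratin genes KRT8 and KRT18 had 165 ± 1.97 and 203 ± 8.08 TPM in wild type and 147 ± 44.8 and 166 ± 22.4 TPM in the knockout-labelled libraries. UCHL1, a neuronal ubiquitin hydrolase, had 329 ± 11.5 and 276 ± 59.7 TPM, and CDKN2A, which encodes the cell cycle inhibitor p16, had 127 ± 3.07 and 101 ± 21.0 TPM. The median over genes of the mean level was 2.28 TPM for undifferentiated monoblast genes, 0.398 for macrophage differentiation markers, 0.599 for pan-leukocyte genes, 0.782 for lymphocyte, 0.134 for granulocyte, 0.249 for erythroid and megakaryocyte, 0.113 for endothelial, 0.487 for fibroblast and stromal and 1.502 for epithelial markers. It was 36.9 TPM for genes of embryonic kidney cell lines, 0.688 for neuroblast, 0.103 for hepatocyte and 0.623 for melanocyte genes. The embryonic kidney list includes abundant genes added after their values had been seen, which raised its median. Of its 8 genes listed before their values were looked at, 4 reached 10 TPM in all 6 libraries, while PAX2, LHX1, EYA1 and INA did not.

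**Figure D2:**
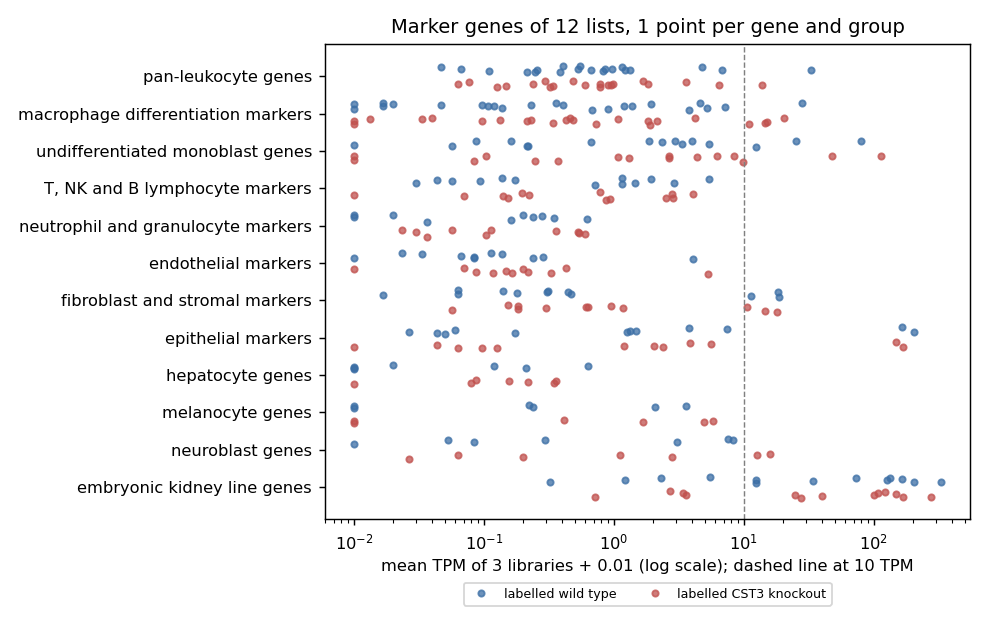
Mean TPM of 3 libraries plus 0.01 on a logarithmic horizontal axis for each gene of 12 marker lists, 1 point per gene and group, with a dashed line at 10 TPM. Pan-leukocyte and macrophage genes lie mostly under 10 TPM in both groups, and 9 of 13 embryonic kidney line genes reach it in all 6 libraries. Among the 8 of these 13 listed before their values were looked at, 4 reach it.

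The expression profiles differed widely between the groups, but knockout-labelled replicate 3 stood apart from its group. Its chi-square statistic per gene was 52.5, 70.6 and 56.9 against wild type replicates 1, 2 and 3. Against knockout-labelled replicates 1 and 2 it was higher, at 101 and 85.0. Pearson's correlations of log2 CPM were 0.968, 0.962 and 0.967 with the wild type libraries, and 0.950 and 0.969 with knockout-labelled replicates 1 and 2. Of 14669 genes tested with edgeR's quasi-likelihood test, 5824 passed a Benjamini-Hochberg adjusted p of 0.05, 3014 higher and 2810 lower in the knockout-labelled libraries. Of these, 1567 changed at least 2-fold, 781 higher and 786 lower. Scaling moved this balance: 51.8% of calls were higher with TMM, the main scaling, and 69.1% with library totals alone. With limma on log2(TPM + 1), which changes the test as well as the scaling, 82.3% were higher. The median log2 fold change over all genes was 0.03 with TMM, 0.22 with library totals alone and 0.33 on log2(TPM + 1). Directions below are therefore relative to the main scaling, and counts of rises and falls on log2(TPM + 1) are given where they tip a list the other way or end a tie. The first principal component held 69.8% of the variance, with wild type libraries at −37.4, −45.3 and −37.7 and knockout-labelled replicates 1, 2 and 3 at 65.9, 49.0 and 5.46. Single libraries moved the counts: 2706, 1838 and 2618 genes passed without wild type replicates 1, 2 and 3, 3033 without knockout-labelled replicate 2 and 9501 without knockout-labelled replicate 3. The count of genes changed at least 2-fold was 822 without wild type replicate 2, 1035 without knockout-labelled replicate 2 and 2958 without knockout-labelled replicate 3.

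Fold changes followed GC content and transcript length. Across 14562 genes, which are not independent replicates, Spearman's correlation of the log2 fold change was −0.60 with GC content and 0.44 with effective length, and both together accounted for 40.6% of the variance. The slope of expression on GC content, in log2 units per 10 percentage points against the wild type mean, was −0.02, 0.05 and −0.02 in wild type replicates 1, 2 and 3 and −0.50, −0.44 and −0.22 in knockout-labelled replicates 1, 2 and 3. The slope per doubling of length was 0.27, 0.26 and 0.09 in the knockout-labelled libraries. After both trends were removed from each library, a step chosen after the data were seen, 3178 genes passed, 1692 higher and 1486 lower, and 37.9% of the 5824 calls passed again in the same direction. This share was 38.1%, 22.7% and 56.1% with knockout-labelled replicates 1, 2 and 3 left out, with 3419, 1784 and 6323 genes passing. With all 6 libraries, corrected changes of at least 2-fold numbered 488, 294 higher and 194 lower. CST3 changed by −0.64 on log2(TPM + 1), by −0.46 ± 0.12 after this correction (edgeR adjusted p = 0.0309) and by −0.35 with the length trend alone removed (edgeR adjusted p = 0.0715). With the GC trend alone removed, CST3 changed by −1.01 ± 0.14 (edgeR adjusted p = 0.00352), close to the main value. Among the 200 genes closest to CST3 in GC content (48.3% to 56.4%) and effective length (574 to 1055 bases), the median log2 fold change was −0.60, and 9% fell more than CST3. Values after removal of both trends are called corrected below.

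**Figure D3:**
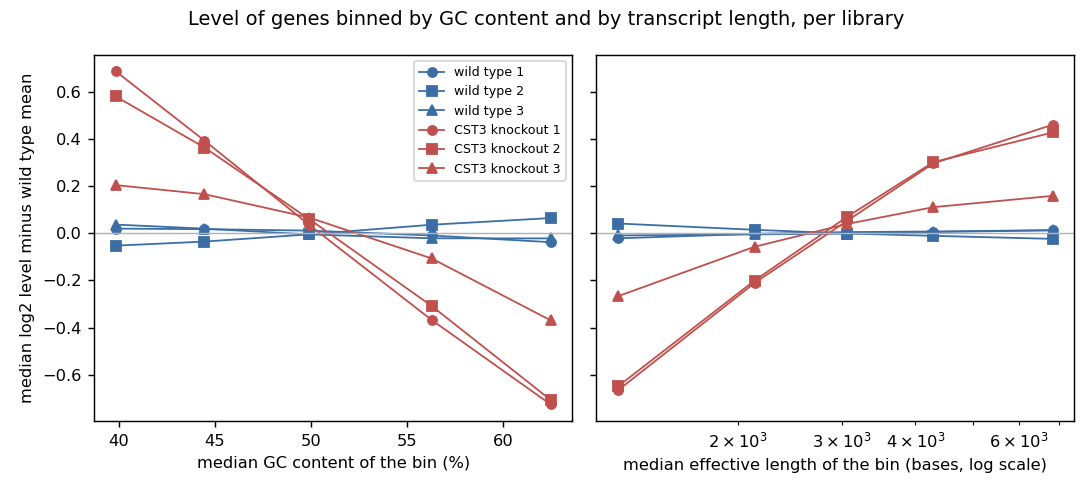
Median log2 ratio to the wild type mean, per library, for genes binned by GC content in percent and by effective length in bases. Lines of the 3 knockout-labelled libraries fall with GC content and rise with length, least in replicate 3, and wild type lines stay near 0.

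Among genes with at least 5 CPM in the higher group, the largest decrease was that of SYNC, which encodes the intermediate filament protein syncoilin and lies on chromosome 1 from 32680360 to 32703596 (GRCh38, minus strand). It had 35.4 ± 2.58 CPM in wild type and 1.92 ± 0.535 CPM in the knockout-labelled libraries (SD, n = 3), a log2 fold change of −4.19 ± 0.22 (edgeR adjusted p = 0.000967) and −4.27 corrected. The chemokine receptor gene CXCR5 followed at −3.33 ± 0.99 (corrected −3.21), with 0, 0.376 and 5.02 CPM in knockout-labelled replicates 1, 2 and 3 against 17.8 ± 1.38 CPM in wild type. SHISA8 changed by −2.63 ± 0.37, AMN by −2.63 ± 0.38, FOXH1 by −2.39 ± 0.36, PLPPR3 by −2.30 ± 0.35, SYTL1 by −2.14 ± 0.28 and CFD, the complement protease factor D, by −2.07 ± 0.36. Their corrected values were −1.85, −1.99, −1.77, −1.67, −1.43 and −1.02. For SHISA8 and PLPPR3 the fall was smaller in TPM. Over replicates 1, 2 and 3, SHISA8 had 26.5, 32.1 and 32.9 TPM in wild type and 6.46, 11.4 and 16.0 TPM in the knockout-labelled libraries. PLPPR3 had 23.9, 32.6 and 29.2 TPM and 7.81, 14.6 and 11.5 TPM. CHAC1, a glutathione-degrading enzyme induced by the integrated stress response, changed by −2.28 ± 0.19, from 97.0 ± 6.02 to 19.9 ± 5.18 CPM (corrected −1.49).

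The largest increases outside overlapping or near-identical genes were those of IGF2BP3, PPTC7 and CRYBG3. The RNA-binding protein gene IGF2BP3 rose from 1.24 ± 0.192 to 20.2 ± 11.1 CPM (SD, n = 3), a log2 fold change of 4.03 ± 0.51 (edgeR adjusted p = 0.00273; corrected 3.47). PPTC7, a mitochondrial phosphatase gene on chromosome 12 from 110533245 to 110583320 (GRCh38, minus strand), rose from 2.37 ± 0.249 to 35.1 ± 8.31 CPM, by 3.88 ± 0.23 (edgeR adjusted p = 0.00152; corrected 3.38). CRYBG3 rose by 3.30 ± 0.50 (corrected 2.64). The other 7 of the 10 largest increases, and EIF4EBP3 among the decreases, overlap or nearly match other genes, so their single-gene values are uncertain. The readthrough gene TVP23C-CDRT4 and TMEFF1 had 0 counts in all wild type libraries and were at least 99.96-fold and 44.3-fold higher against a floor of 3 counts per library, but the log2 fold change was 0.14 for TVP23C-CDRT4 summed with TVP23C and CDRT4 (edgeR adjusted p = 0.537) and 0.86 for TMEFF1 summed with MSANTD3-TMEFF1. CSNK2A3 changed by 6.75 ± 0.73 alone and by 0.42 summed with CSNK2A1, BMI1 by 4.34 ± 0.85 and 0.80 summed with COMMD3-BMI1, and HNRNPH2 by 3.68 ± 0.47 and 1.06 summed with RPL36A-HNRNPH2. NOMO3 changed by 4.55 ± 0.79 alone and by 1.496 summed with NOMO1 and NOMO2, and NBPF10 by 3.49 ± 0.79 alone and by 0.82 as the sum of 14 NBPF genes. EIF4EBP3 changed by −2.08 ± 0.29 alone and by 0.34, the other direction, summed with ANKHD1 and ANKHD1-EIF4EBP3.

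**Figure D4:**
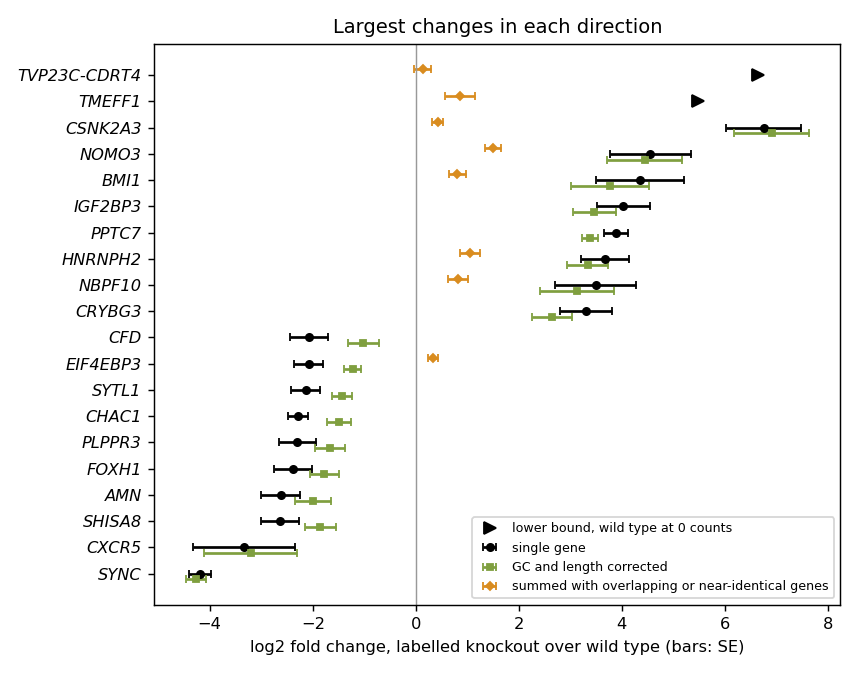
Log2 fold change, knockout-labelled over wild type, of the 10 largest increases and 10 largest decreases, with SE bars, beside corrected values and values of summed genes. TVP23C-CDRT4 and TMEFF1, at 0 in wild type, are drawn as lower bounds, and sums lie far nearer 0 than the single genes.

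Of the cystatin family, 3 genes other than CST3 were tested, and 1, CSTB, the gene of the intracellular inhibitor cystatin B, fell. CSTB went from 168 ± 4.35 to 104 ± 25.7 CPM (SD, n = 3), a log2 fold change of −0.69 ± 0.17 (edgeR adjusted p = 0.0167), and stood at 0.04 corrected (edgeR adjusted p = 0.779). CST1 (−1.08 ± 0.52) and CSTA (0.23 ± 0.62) did not pass. Among 10 cysteine cathepsins and legumain, the proteases cystatins inhibit, 1 rose, 1 fell and 8 did not pass with edgeR, 2 had an unadjusted p under 0.05, and 0 passed adjusted over the list alone. DESeq2 and limma-voom each also called 1 rise and 1 fall. On log2(TPM + 1) 5 rose and 0 fell. The legumain gene LGMN rose from 63.5 ± 2.95 to 84.4 ± 12.1 CPM, by 0.41 ± 0.13 (edgeR adjusted p = 0.0393; corrected 0.58). CTSH fell from 120 ± 4.63 to 72.4 ± 20.4 CPM, at −0.73 ± 0.20 (edgeR adjusted p = 0.0225), and the corrected value of −0.46 had an edgeR adjusted p of 0.0514. Values of the others were −0.28 ± 0.18 for CTSB, 0.02 ± 0.14 for CTSC, 0.13 ± 0.16 for CTSF, 0.35 ± 0.19 for CTSK, 0.07 ± 0.11 for CTSL, 0.71 ± 0.53 for CTSO, 0.66 ± 0.37 for CTSS and −0.05 ± 0.12 for CTSV. Corrected values passed for CTSC (−0.37), CTSF (0.58) and CTSV (−0.50).

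Of 36 lysosomal hydrolases and membrane proteins, 6 rose, 7 fell and 23 did not pass, with 6 and 7 adjusted over the list alone, 14 and 2 on log2(TPM + 1), and 3 and 4 corrected. The alpha-mannosidase gene MAN2B1 changed by −1.05 ± 0.25 (corrected −0.71). Of 16 subunits of the vacuolar proton pump, 5 rose and 2 fell, and the counts were 5 and 2 both adjusted over the list alone and corrected. ATP6V1B2 rose by 0.82 ± 0.11 (corrected 0.58), and ATP6V1F changed by −0.85 ± 0.24 but by −0.06 corrected, which did not pass. Of 25 autophagy genes, 8 rose and 3 fell, the same counts adjusted over the list alone, and 6 rose and 4 fell corrected. The conjugation factor gene ATG16L1 rose by 0.89 ± 0.15 and GABARAPL1 by 0.85 ± 0.20 (corrected 0.81 and 0.95), while ATG7 changed by −0.83 ± 0.11 (corrected −1.04; −0.15 on log2(TPM + 1), not passing).

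In the 13 MHC class II presentation genes, 0 rose and 2 fell with edgeR, 0 and 1 adjusted over the list alone, 2 and 1 on log2(TPM + 1), and 1 and 0 corrected. The invariant chain gene CD74 went from 2.30 ± 0.585 to 0.749 ± 0.185 CPM (SD, n = 3; −1.61 ± 0.33; corrected −0.96, edgeR adjusted p = 0.0828). HLA-DQB1 changed by −0.39 ± 0.12, and by 0.07, the other direction, on log2(TPM + 1). Of 14 MHC class I genes, 3 fell and 0 rose with edgeR, the same counts adjusted over the list alone, but 5 rose and 0 fell on log2(TPM + 1) and 3 rose and 0 fell corrected. The immunoproteasome gene PSMB10 changed by −0.93 ± 0.16 (corrected 0.02) and the tapasin gene TAPBP by −0.65 ± 0.16 (corrected −0.31, neither passing). Of 26 interferon-stimulated genes, 4 rose and 4 fell, 4 and 2 adjusted over the list alone, 7 and 2 on log2(TPM + 1), and 2 rose and 0 fell corrected. The ubiquitin-like ISG15 went from 27.8 ± 2.99 to 7.74 ± 0.841 CPM, at −1.85 ± 0.16 (edgeR adjusted p = 0.00194), and −0.55 corrected (edgeR adjusted p = 0.0642). IFI27 changed by −1.69 ± 0.23 (corrected −0.68, not passing) and HERC5 rose by 0.95 ± 0.17 (corrected 0.47).

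Of 23 inflammatory cytokines and NF-kB targets, 5 rose and 5 fell, also adjusted over the list alone, 5 and 3 on log2(TPM + 1), and 4 and 2 corrected. TNFAIP3, an inhibitor of NF-kB signalling, rose by 1.44 ± 0.22 (corrected 1.25) and NFKB1 by 1.36 ± 0.34 (corrected 1.18), both from under 10 CPM, while G0S2 changed by −1.51 ± 0.36 (corrected −0.78, not passing). Rises and falls were 1 and 0 of 8 chemokines (0 and 0 adjusted over the list alone with 1 at an unadjusted edgeR p under 0.05, 0 and 0 with DESeq2, 1 and 0 with limma-voom, corrected 1 and 0), 3 and 1 of 8 alternative activation markers (3 and 1 adjusted over the list alone, corrected 2 and 0) and 2 and 1 of 8 inflammasome genes (2 and 1 adjusted over the list alone, corrected 1 and 0). They were 1 and 4 of 19 pattern recognition genes (0 and 4 adjusted over the list alone, 6 and 1 on log2(TPM + 1), corrected 0 and 2) and 1 and 3 of 16 phagocytosis genes (1 and 3 adjusted over the list alone, 5 and 1 on log2(TPM + 1), corrected 1 and 3). They were 2 and 2 of 13 complement genes, 2 and 1 adjusted over the list alone, 4 and 1 on log2(TPM + 1) and 2 and 2 corrected. CYBA, a subunit of the phagocyte oxidase, went from 388 ± 33.0 to 137 ± 20.7 CPM (−1.51 ± 0.14; corrected −0.36, not passing). Of 12 macrophage differentiation markers, 2 rose and 1 fell, also adjusted over the list alone, and 1 and 0 corrected. GPNMB rose by 1.01 ± 0.28 (corrected 0.70, not passing), while the lipopolysaccharide co-receptor gene CD14, at 1.93 ± 0.458 TPM in wild type, changed by −1.37 ± 0.35 (corrected −0.88, not passing). Rises and falls were 2 and 1 of 11 monoblast genes (1 and 0 adjusted over the list alone, corrected 2 and 0), 3 and 3 of 14 lipid-associated macrophage genes (3 and 3 adjusted over the list alone, 7 and 2 on log2(TPM + 1), corrected 2 and 1) and 7 and 2 of 20 microglial genes linked to neurodegeneration (7 and 3 adjusted over the list alone, corrected 1 and 1).

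Of 24 cholesterol biosynthesis genes, 9 rose, 5 fell and 10 did not pass, 9 and 7 adjusted over the list alone, and 6 rose and 0 fell corrected. The sterol oxidase gene MSMO1 rose from 44.1 ± 2.52 to 116 ± 28.2 CPM (SD, n = 3), by 1.39 ± 0.19 (edgeR adjusted p = 0.00295; corrected 1.06). INSIG1, a sterol-sensing regulator, rose by 1.21 ± 0.23 (corrected 1.05), SQLE, a rate-limiting enzyme, by 1.14 ± 0.24 (corrected 0.92) and the sterol carrier gene STARD4 by 1.40 ± 0.34 (corrected 0.72, not passing). The list as a set did not pass camera (adjusted p = 0.896; 0.0110 without knockout-labelled replicate 3). Its corrected camera adjusted p was 0.0748, and 3.00e-07 without knockout-labelled replicate 3. With all 6 libraries and an estimated correlation, the corrected camera adjusted p was 0.950. Of 14 LXR targets, 3 rose and 3 fell, also adjusted over the list alone, 5 and 2 on log2(TPM + 1), and 3 and 1 corrected. The cholesterol exporter gene ABCA1 rose by 1.48 ± 0.36 and SMPDL3A by 1.28 ± 0.24 (corrected 1.08 and 1.15), and the phospholipid transfer protein gene PLTP changed by −1.28 ± 0.18 (corrected −0.74). APOE, at 28.1 ± 1.30 TPM in wild type, had −0.83 ± 0.31 and did not pass.

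Of 15 matrix metalloproteinases, relatives and inhibitors, 2 rose and 1 fell, also adjusted over the list alone and corrected. ADAM17, the sheddase of TNF, rose from 3.07 ± 0.475 to 19.8 ± 7.79 CPM (SD, n = 3), by 2.69 ± 0.34 (edgeR adjusted p = 0.00273; corrected 2.16), and ADAM9 rose by 1.24 ± 0.28 (corrected 0.86), while MMP19 changed by −1.18 ± 0.20 (corrected −1.11). Of 27 genes of TGF-beta signalling, 7 rose and 2 fell, also adjusted over the list alone, and 5 and 2 corrected. The matricellular protein gene CCN2 rose by 1.56 ± 0.47 and the inhibitory SMAD7 by 1.07 ± 0.15 (corrected 1.55 and 1.40), and THBS1 by 1.55 ± 0.50 (corrected 1.22, not passing). Of 38 cell cycle genes, 15 rose, 5 fell and 18 did not pass, 15 and 6 adjusted over the list alone, and 13 and 4 corrected. The list did not pass camera (adjusted p = 0.208), but did with the length trend alone removed (camera adjusted p = 0.0254). With an estimated correlation the camera adjusted p was 0.962, and 0.950 corrected. CCNE2, a cyclin of the G1/S transition, rose by 2.11 ± 0.33, the centromere motor gene CENPE by 1.36 ± 0.32 and KIF23, which acts in cytokinesis, by 1.10 ± 0.16 (corrected 1.58, 0.63 and 0.64). TOP2A rose from 249 ± 15.9 to 490 ± 96.2 CPM, by 0.98 ± 0.16 (corrected 0.37). Of 26 p53 targets and apoptosis genes, 10 rose and 5 fell, 11 and 6 adjusted over the list alone, and 5 and 1 corrected. The ribonucleotide reductase gene RRM2B rose by 1.28 ± 0.36 (corrected 0.63, not passing) and the stress-induced SESN2 changed by −1.19 ± 0.13 (corrected −0.90).

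Ribosomal protein and oxidative phosphorylation genes were the only lists called of 35 tested with camera at its preset correlation. For 7 lists that did not pass (interferon-stimulated, pattern recognition, phagocytosis, lipid-associated macrophage, LXR, unfolded protein response, and glycolysis and hypoxia genes) the median lay above 0 and camera's direction was down. Of 34 ribosomal protein genes, 0 rose and 19 fell with edgeR, 0 and 24 adjusted over the list alone, with a median log2 fold change of −0.70 (−0.52 with library totals alone and −0.28 on log2(TPM + 1), where 0 rose and 15 and 9 fell). The camera adjusted p was 1.37e-06, and the adjusted p was 0.962 with an estimated correlation. The share of counts on ribosomal protein genes was 20.1%, 21.3% and 20.5% in wild type and 12.9%, 11.9% and 18.7% in knockout-labelled replicates 1, 2 and 3. Corrected, 4 rose and 11 fell, the median was −0.12 and the camera adjusted p 0.194, but 8.44e-05 without knockout-labelled replicate 3. With all 6 libraries and an estimated correlation, the corrected camera adjusted p was 0.950. RPS15 changed by −1.12 ± 0.22 (corrected 0.20, not passing) and RPL37 by −0.97 ± 0.25 (corrected −1.40), and RPS2, at −0.46 ± 0.24, did not pass but rose by 0.40 corrected. Of 33 nuclear genes of oxidative phosphorylation, 3 rose and 21 fell, 3 and 22 adjusted over the list alone, with a median of −0.59 (−0.41 with library totals alone, where 3 rose and 16 fell, and −0.14 on log2(TPM + 1), where 5 rose and 7 fell). Their camera adjusted p was 0.000170, and the adjusted p was 0.962 with an estimated correlation. Corrected, 1 rose and 8 fell, the median was −0.13 and the camera adjusted p 0.175. With the GC trend alone removed, the ribosomal and oxidative phosphorylation medians were −0.71 and −0.58. Both lists then passed (camera adjusted p = 5.71e-09 and 3.79e-09). With the length trend alone removed, the medians were −0.14 and 0.06, and neither passed (camera adjusted p = 0.909 and 0.962). The loss of both calls thus came with the length term. The complex I genes NDUFB10 and NDUFA1 changed by −1.32 ± 0.32 and −1.31 ± 0.36 and the complex IV gene COX5B by −1.15 ± 0.14 (corrected −0.37, −0.42 and −0.48, of which COX5B passed), and ATP5F1B, at −0.13 ± 0.12, did not pass.

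**Figure D5:**
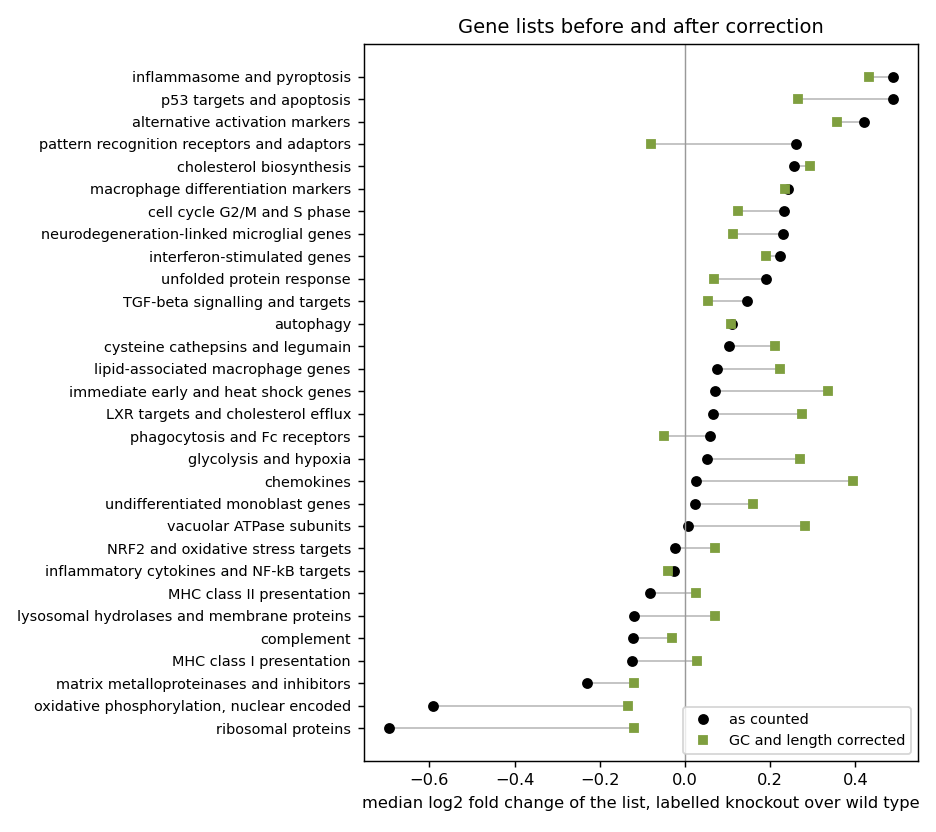
Median log2 fold change per gene list, knockout-labelled over wild type, before and after correction for GC content and length. Ribosomal protein and oxidative phosphorylation lists move from −0.70 and −0.59 to −0.12 and −0.13. With the GC trend alone removed, which is not drawn, they stay at −0.71 and −0.58.

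Of 25 unfolded protein response genes, 5 rose and 6 fell, 6 and 6 adjusted over the list alone, 12 and 4 on log2(TPM + 1), and 2 and 3 corrected. SDF2L1, a chaperone cofactor, changed by −1.33 ± 0.20 and the pseudokinase gene TRIB3 by −1.12 ± 0.23 (corrected −0.16 and −0.50, neither passing). Of 28 glycolysis and hypoxia genes, 6 rose and 5 fell, also adjusted over the list alone, and 7 and 3 corrected. Hexokinase HK2 rose by 1.22 ± 0.21 and PGK1 by 1.09 ± 0.20 (corrected 1.01 and 0.61). GAPDH, often used as a reference gene, went from 5809.8 ± 287 to 2794 ± 508 CPM (SD, n = 3), at −1.06 ± 0.19 (edgeR adjusted p = 0.00556; corrected −0.46). Of 23 NRF2 targets, 3 rose and 5 fell, also adjusted over the list alone, 7 and 1 on log2(TPM + 1), and 2 and 2 corrected. The thioredoxin reductase gene TXNRD1 rose by 0.84 ± 0.22 (corrected 0.48, not passing). The directional test fry called the NRF2 targets lower (adjusted p = 0.0233), and camera did not. Of 25 immediate early and heat shock genes, 4 rose and 3 fell, also adjusted over the list alone, and 6 and 0 corrected. The list did not pass camera (adjusted p = 0.937), and its corrected camera adjusted p was 0.194, but 1.02e-05 without knockout-labelled replicate 1. With all 6 libraries, camera with an estimated correlation gave an adjusted p of 0.962, and 0.950 corrected. HSPA1B, uncertain because HSPA1A is nearly identical, changed by 1.32 ± 0.42, and by 1.31 summed with HSPA1A, while HSPB1 changed by −1.24 ± 0.39 (corrected −0.24, not passing).

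Of 15 genes near CST3 on chromosome 20, 2 rose and 3 fell, 2 and 2 adjusted over the list alone, 3 and 0 on log2(TPM + 1), and 2 and 1 corrected. The exonuclease gene XRN2 rose by 1.19 ± 0.19 and NAPB by 0.93 ± 0.22 (corrected 0.76 and 0.43, XRN2 passing), and ENTPD6 changed by −0.79 ± 0.12 and ABHD12 by −0.63 ± 0.15 (corrected −0.45 and −0.27, ENTPD6 passing). Among marker lists of other cell types, rises and falls were 0 and 1 of 7 epithelial (0 and 1 adjusted over the list alone, 1 and 0 on log2(TPM + 1), 0 and 0 corrected), 1 and 1 of 8 fibroblast and stromal (0 and 0 adjusted over the list alone, 3 and 0 on log2(TPM + 1), 0 and 0 corrected, with 4 at an unadjusted edgeR p under 0.05), and 0 and 1 of 2 erythroid and megakaryocyte genes (0 and 1 adjusted over the list alone, 0 and 0 on log2(TPM + 1), 1 and 0 corrected). Of 5 endothelial, 7 lymphocyte and 3 granulocyte genes, 0 passed with edgeR, adjusted over all genes or adjusted over the list alone, and 1, 2 and 0 had an unadjusted p under 0.05. DESeq2 called 1, 1 and 0 of them and limma-voom 0, 1 and 0, and on log2(TPM + 1) 1 gene of each list rose and 0 fell. Corrected, 0 endothelial and 0 granulocyte genes passed with edgeR, and 1 lymphocyte gene rose and 1 fell.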

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

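The corrections for GC content and length and the summing of genes were chosen after the data were seen, and the other alternatives before. CST3 stayed lower in every alternative, at −1.18 to −0.89 with 1 library left out and −0.64 on both TPM scales, and missed the threshold with the length correction alone (−0.35) and in the test against a 1.5-fold or 2-fold change (edgeR adjusted p = 0.0606 and 1). With the GC correction alone, CST3 stood at −1.01 (edgeR adjusted p = 0.00352). The main counts were 5824 genes changed, 1567 at least 2-fold, and 2 lists. With 1 library left out they ranged from 1838 (without wild type replicate 2) to 9501 (without knockout-labelled replicate 3), from 822 to 2958 for the same libraries, and from 2 to 3 lists. The edgeR test against 1.5-fold left 628 genes and that against 2-fold 12, as stricter tests, and log2(TPM + 0.1) gave 2838 genes at least 2-fold. The GC and length correction gave 3178 genes and 488 at least 2-fold, and the latter were 698 with the GC correction alone and 1026 with the length correction alone. With the correction and without knockout-labelled replicates 1, 2 and 3, counts were 3419, 1784 and 6323 genes, and 430, 334 and 1013 at least 2-fold. Lists called by camera were 0 with an estimated correlation (0 at an unadjusted p under 0.05), 0 corrected (7 unadjusted), 1 with the length correction alone (cell cycle), 1 corrected without knockout-labelled replicate 1 (immediate early and heat shock), 0 corrected without replicate 2 (4 unadjusted), 2 corrected without replicate 3 (cholesterol biosynthesis and ribosomal proteins) and 0 corrected with an estimated correlation (0 unadjusted); fry called 2 (8 unadjusted), oxidative phosphorylation and NRF2 targets (both adjusted p = 0.0233), and not ribosomal proteins (0.187). With the GC correction alone, camera called 2 lists, ribosomal proteins and oxidative phosphorylation. Where no construction is named, the cause was not tested.

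HLA-DQB1 turned to 0.067 on log2(TPM + 1) and 0.069 on log2(TPM + 0.1). With the GC and length correction, and then without knockout-labelled replicates 1, 2 and 3, CSTB stood at 0.036, 0.0032, 0.027 and 0.054 (0.15 with the length correction alone), CTSC at −0.37, −0.34, −0.41 and −0.35 (−0.41 with the GC correction alone), RPS15 at 0.20, 0.085, 0.20 and 0.27 and RPS2 at 0.40, 0.36, 0.46 and 0.38. PSMB10 stood at 0.019 corrected and 0.22 corrected without replicate 3, and EIF4EBP3 at 0.34 when summed. Of 78 named genes called, DESeq2 kept 77, limma-voom 75, library totals alone 77, log2(TPM + 1) 69 and the correction 53. Leaving out wild type replicates 1, 2 and 3 kept 55, 49 and 54, and leaving out knockout-labelled replicates 1, 2 and 3 kept 73, 49 and 78, with fewer samples.

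Same-numbered libraries did not deviate together (correlations across genes of 0.02, −0.15 and −0.09). This gave no sign that the numbers paired the samples, but with 3 libraries per group it cannot exclude pairing. With the replicate block, 5002 genes passed, 1620 at least 2-fold, CST3 stood at −1.07 and 2 lists were called. Library totals were so alike that thinning to the smallest did not test depth, and genes under about 1 CPM, such as THBS1 and CST1, rest on few counts.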

Other observations

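The tests of gene families, of the trend, of CST3 against it and of list genes with a row were chosen after the results were seen, and the splits before. Those of depth and of RNA from other cells were chosen after low leukocyte levels had been seen, with their predictions written before the values tested, which for the latter were those of 8 of 13 list genes. Gene families defined by symbol root were tested with camera, 188 in all, of which 16 passed and 11 passed corrected for GC content and length, while the lowest adjusted p was 0.735 with an estimated correlation after correction. The 11 include the CDKN and OR genes, which passed only after correction (camera adjusted p = 0.0430 and 0.00107, against 0.752 and 0.558 before it). Mitochondrial ribosomal proteins of the large subunit (MRPL) fell in 29 of 49 genes and rose in 1, with a median log2 fold change of −0.56 (−0.17 on log2(TPM + 1); corrected −0.20 with 1 rise and 12 falls, camera adjusted p = 0.0220). Those of the small subunit (MRPS) fell in 18 of 29 and rose in 1 (median −0.54; −0.06 on log2(TPM + 1); corrected −0.22 with 2 rises and 10 falls, camera adjusted p = 0.00598). The NDUFA genes of complex I fell in 12 of 14 (median −0.88; −0.44 on log2(TPM + 1); corrected −0.55 with 1 rise and 8 falls, camera adjusted p = 0.000782), and the NDUFB genes, also of complex I, in 9 of 11, with 1 rise (median −0.80; −0.39 on log2(TPM + 1)), a call not kept after correction (median −0.14, 1 rise and 1 fall, camera adjusted p = 0.748). The RPL genes, most of which encode proteins of the large cytoplasmic ribosomal subunit, fell in 26 of 50 and rose in 1 (median −0.74; −0.33 on log2(TPM + 1); corrected −0.24 with 2 rises and 14 falls, camera adjusted p = 0.00231), and the RPS genes, most of them of the small subunit, fell in 24 of 43 and rose in 3 (median −0.67; −0.25 on log2(TPM + 1); corrected −0.025 with 5 rises and 11 falls, camera adjusted p = 0.496). The KDM genes, most of which encode histone lysine demethylases, rose in 11 of 17 and fell in 0 with edgeR (median 0.51; corrected 0.44 with 9 rises and 0 falls), and the TAF genes, many of which encode subunits of the transcription factor TFIID, rose in 14 of 23 and fell in 3 (median 0.62; corrected 0.53 with 10 rises and 1 fall). Both had a corrected camera adjusted p of 0.000782.

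Families that hold near-identical copies, whose single-gene values are uncertain, moved in opposite directions. They were grouped by symbol root alone, so not every member, as among the GOLGA genes, need be such a copy. The NPIPB genes fell in 9 of 11 (median −0.93, −0.39 on log2(TPM + 1); corrected −0.89 with 0 rises and 8 falls, camera adjusted p = 2.53e-11). The NBPF genes rose in 10 of 12 (median 1.09; corrected 0.79 with 9 rises and 0 falls, camera adjusted p = 0.000223), and the GOLGA genes in 10 of 27 (median 0.62; corrected 0.33 with 6 rises and 0 falls, camera adjusted p = 0.0218). With an estimated correlation the corrected camera adjusted p was 0.735 for NPIPB and 0.845 for both NBPF and GOLGA.

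Leukocyte and macrophage transcripts were near the floor in all 6 libraries. Depth was excluded as the reason, since 10 TPM gave at least 304 counts, and so were missing genes, since 93.3% of the 45 pan-leukocyte and macrophage genes had a row. A candidate explanation is RNA from cells other than macrophages: 4 of 8 embryonic kidney line genes not looked at before (among them CDH2, UCHL1 and CDKN2A, the last at 127 ± 3.07 TPM in wild type and known as deleted in THP-1) reached 10 TPM in all libraries, exactly the minimum set beforehand for this explanation. PAX2, LHX1, EYA1 and INA, also among the 8, stayed under 10 TPM, with wild type means of 5.49, 2.29, 1.21 and 0.310 TPM. The list also holds NEFM, NEFL and GAL, seen before, at 72.3, 34.0 and 133 TPM in wild type. Of the list's 13 genes, 2, KRT8 and KRT18, are also in the epithelial list, UCHL1 at 329 TPM was the most abundant, and the remaining lists had medians under 3 TPM, but these genes do not single out 1 line. The labels name no sort, and both groups share the pattern. The median of 0.531 TPM over the 42 pan-leukocyte and macrophage genes, beside the CDKN2A level, argues against RNA mainly from THP-1 macrophages. Where the RNA came from was not tested, so an exchange of cells or of the table stays a hypothesis.

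Fold changes followed GC content and transcript length. After the fitted trend was removed, 37.9% of the calls passed in the same direction (22.7% to 56.1% with 1 knockout-labelled library left out). The fitted trend thus did not account for all calls. The correction covers only additive trends in GC content and effective length, and bias of another form could remain. Such bias as the whole cause of the calls was therefore not excluded. A difference in library making or RNA quality could give such a trend: the GC slopes were −0.50, −0.44 and −0.22 in the knockout-labelled libraries, against −0.02 to 0.05 in wild type. All 3 lie outside the wild type range, so this cannot be told apart from an effect of the group, which stays open and untested. The partial loss of CST3 may also follow the trend in part, since 9% of 200 genes alike in GC content and length fell more, and the corrected change of −0.46 passed while that with the length correction alone, −0.35, did not. With the GC correction alone, CST3 stood at −1.01 and passed, so the weakening came with the length term.

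The 10 splits of the 6 libraries into groups of 3 are too few for a share under 0.05. Every other split mixes both groups, so the group difference adds to the spread within each side and lowers the gene calls. The low gene counts of those splits therefore say nothing about the cause of the difference. For genes changed, 1 split, the real one, gave as many (5824), and the highest other gave 0 with edgeR, or 955 at an unadjusted p under 0.05 against 7388. For changes of at least 2-fold, 1 split gave as many (1567, highest other 0, or 218 unadjusted against 1674). For lists, 7 splits gave as many as the real 2, and the highest other, which set wild type replicates 1 and 2 and knockout-labelled replicate 1 against the rest, gave 9.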
